A study of Arabidopsis thaliana with 21 samples.

How the data were processed

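The 21 samples fall into 9 groups, of which 4 eCLIP groups (2 samples each) and 2 total RNA conditions (2 samples each) entered the comparisons. Upstream, reads were handled with Trimmomatic 0.39, HISAT2 2.2.0 and SAMtools on the TAIR10 genome, per the submitters' processing notes. Whether PCR duplicates were removed is not stated. Of the reads assigned to genes, 0.938% (herboxidiene) to 2.45% (wild type) repeated the strand, start, end and molecular identifier of another read, and all were counted. For eCLIP, the authors deposited 1 line per read, with the class of the read, its gene, exon or intron and its distance to the exon end. These are not normalised values, and every read count was made here from those lines. The deposited eCLIP sets are in 2 parts, 1 with reads assigned to genes as exonic, spliced, exon-intron boundary or intronic, and 1 with the remaining reads, such as those on single-exon transcripts or outside genes. The authors merged the replicates of each eCLIP group, so samples could not be separated. For total RNA, the deposited tables give a pair of read counts, spliced and unspliced, and the ratio of unspliced to spliced reads at both splice sites of each intron, with 1 value per condition. How the samples of a condition were combined is not stated. The 2 columns with the ratio at the 3′ splice site were not used, since the 3′ values were computed from the read counts. The mRNA samples were not analysed here.

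The main measure in total RNA was the unspliced share at the 5′ splice site, unspliced reads divided by unspliced plus spliced reads, because the planned difference of 0.1 had assumed a share, while the deposited ratio has no upper limit. It was computed for introns with at least 10 reads in both conditions. Of 121244 introns listed in 22121 genes, 74 that end before their start were left out and 34 listed again for the same gene were counted once, leaving 121136. An intron shared by overlapping genes was counted for each gene. The authors left 45906 introns without a count with DMSO and 59557 with herboxidiene. Transcript levels in total RNA were approximated by spliced junction reads per gene over introns counted in both conditions, scaled to the total of such reads.

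For eCLIP, the share of each class was taken of all reads and of reads assigned to genes. The position of a read was its start, counted upstream from the last base of the exon. The authors counted a gene on different transcripts in different groups, for 1251 of 11294 genes (11.1%) between eIF4A3-FLAG and wild type and for 1055 of 14493 (7.28%) between herboxidiene and DMSO. With herboxidiene, UBQ11 and JAZ1 had 2167 and 700 reads in the single-exon class and none assigned to exons. Reads per gene were therefore the reads assigned to the gene plus the remaining reads that started inside the span of exactly 1 gene on its strand, a choice made after the data were seen. Ribosomal DNA was taken as chromosome 2 from 1 to 10000 and chromosome 3 from 14190001 to 14210000. Gene ratios were computed relative to the total of nuclear protein-coding reads for genes with at least 100 reads in both groups together. The totals covered nuclear protein-coding genes to which at least 1 read was assigned in any eCLIP group. They were 98410 in wild type, 1927664 in untreated eIF4A3-FLAG, 946454 with DMSO and 796938 with herboxidiene. Genes with reads in the remaining part alone, such as single-exon genes, were in neither these totals nor the gene counts. The single-exon class made up 16.2% of all reads in wild type, 8.00% in untreated eIF4A3-FLAG, 8.25% with DMSO and 13.1% with herboxidiene. A count of 0 was given a floor of 3 reads, which lies inside the exact interval of such a count. Ratios carry exact conditional binomial (Clopper-Pearson) 95% intervals, and shares carry Wilson 95% intervals. Symbols came from a table that pairs locus identifiers with names, and coordinates from the deposited tables in TAIR10.

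The measures of each comparison, the lists and the rule for named genes were fixed before the data were examined, apart from the choices named here and in the closing parts as made later. Named genes are the 10 with the highest lower bound and the 10 with the lowest upper bound of the interval per eCLIP comparison. Named introns are the 10 entries with the largest difference in each direction among those with at least 50 reads in both conditions. An intron shared by overlapping genes is an entry for each gene. Of each gene list, 2 to 4 members with most reads are named. EIF4A-III is always given. Other list members and genes were named after their values were seen, because they are the few that pass a threshold or fail to, or stand out. The lists were SR proteins, exon junction complex and nonsense-mediated decay factors, nuclear photosynthesis genes, clock genes, heat shock genes, ABA and osmotic stress genes, SF3B factors and cytosolic ribosomal proteins. A list's median was placed among 10000 random lists of the same size, matched in 10 bins of expression (seed 1). Intronless genes could not be compared as a list, as no annotation was given.

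Calculations used Python 3.11.15, NumPy 2.4.6, pandas 2.3.3, SciPy 1.17.1 and Matplotlib 3.10.9. The gene and intron steps were tested on simulated data. For eIF4A3-FLAG against wild type, 98% of 100 genes set 4-fold higher and 100% of 61 set lower were recovered, and 5.46% of unchanged genes were counted as 2-fold different. Intervals held the true ratio for 96.8% of genes. For herboxidiene against DMSO, 100% were recovered in both directions, 0% of unchanged genes were counted, and 95.7% of intervals held the true ratio. The simulated gene counts held counting error alone, so these rates leave out variation between samples. They were modelled on the reads assigned to genes, without the remaining reads that were added to the gene counts. Of 200 introns raised by 30 points, 97% were recovered, while 6.52% of unchanged introns counted as higher and 6.08% as lower. Alternatives covered scaling by the median of ratios, other read minimums, exonic reads alone, 1 of the deposited parts alone, genes on the same transcript, the flow cell shared with wild type, other windows and exons, the 3′ splice site, the deposited ratio, and intervals that lie apart.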

Results

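The series profiled where the RNA helicase eIF4A3, a core subunit of the exon junction complex, contacts RNA in 7-day-old Arabidopsis seedlings of the Col-0 ecotype. Reads were obtained by eCLIP, in which RNA crosslinked to a protein is recovered by immunoprecipitation and sequenced. A FLAG antibody was used on plants carrying eIF4A3-FLAG and on wild-type plants without a tag, which give the background of the pull-down. The 4 eCLIP groups were wild type, untreated eIF4A3-FLAG, and eIF4A3-FLAG treated with DMSO or with herboxidiene, a compound that inhibits splicing. Each group had 2 samples whose reads were merged into 1 pooled set. The pooled sets held 195665 reads for wild type, 2522088 for untreated eIF4A3-FLAG, 1226738 for DMSO and 1175823 for herboxidiene. Total RNA of eIF4A3-FLAG plants treated with DMSO or herboxidiene (2 samples each) was measured as 1 pair of spliced and unspliced read counts per intron and condition. At the 5′ splice sites these comprised 3331241 spliced and 166761 unspliced reads with DMSO, and 1716228 and 225749 with herboxidiene. The series also holds 9 mRNA samples in 3 groups of 3 (eIF4A3-FLAG, and eif4a3 RNAi plants given ethanol or beta-estradiol), which were not analysed here. Intervals are 95% intervals and cover counting error only, unless resampling of genes is named. With 1 pooled set per group, no difference could be compared with the spread between replicates, and no gene was tested. Gene lists were placed among random lists of genes, which are not independent replicates.

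The comparison of eIF4A3-FLAG with wild type asks which reads depend on the tag. Spliced reads made up 33.6% (Wilson interval 33.5 to 33.7) of all reads from untreated eIF4A3-FLAG plants and 5.18% (5.08 to 5.27) of those from wild type. Among reads assigned to genes, the spliced shares were 46.2% and 10.5%. Reads with intron sequence, at exon-intron boundaries or within introns, were 5.00% of the eIF4A3-FLAG reads assigned to genes and 13.6% of the wild-type reads. Wild-type reads included 11163 organellar reads and 47963 reads in the ribosomal DNA regions, together 30.2% of its reads. The untreated eIF4A3-FLAG set held 0 organellar and 62 ribosomal DNA reads. Without these reads the spliced share of wild type was 7.42%. Wild type also had few reads that started very near an exon end, as given below. Such reads mostly cross the exon end, so their lack can lower the spliced share of wild type.

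Reads from tagged plants started most often shortly before the 3′ end of exons, where the exon junction complex is known to be deposited upstream of splice junctions. Of the reads on exons other than the last, 20.7% (20.6 to 20.8) started 35 to 15 nt upstream of the exon end in untreated eIF4A3-FLAG, and 5.28% (5.11 to 5.46) in wild type, a ratio of 3.92 (3.79 to 4.05). In all 3 tagged groups the most frequent start was 28 nt upstream of the exon end, with a smaller maximum at 19 nt. Wild type had few starts within 16 nt of the exon end, with 0.042% of reads at 16 nt and 0.252% at 19 nt. Untreated eIF4A3-FLAG had 0.702% and 0.987% at these positions. The cause of this step in wild type, which lies inside the window and next to the 19 nt maximum, was not tested. The window of 30 to 20 nt, which leaves the step out, gave a ratio of 3.85 (3.69 to 4.03). First exons had 13.8% of their reads in the window of 35 to 15 nt in eIF4A3-FLAG and 2.57% in wild type. For internal exons the shares were 22.6% and 6.95%. The window 65 to 45 nt upstream held 12.7% and 6.09%, a ratio of 2.08 (2.01 to 2.14). Last exons took 12.4% of exonic reads in eIF4A3-FLAG and 27.0% in wild type. On the flow cell that both groups shared, the ratio at exon ends was 3.94 and the spliced share of reads assigned to genes was 43.7% against 10.5%. Untreated eIF4A3-FLAG was sequenced on 3 flow cells, and on the others its spliced share was 48.9% and 51.0%. The intervals leave out this spread. Its share at exon ends was 20.8% on the shared flow cell and 20.3% and 20.6% on the others.

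**Figure D1:**
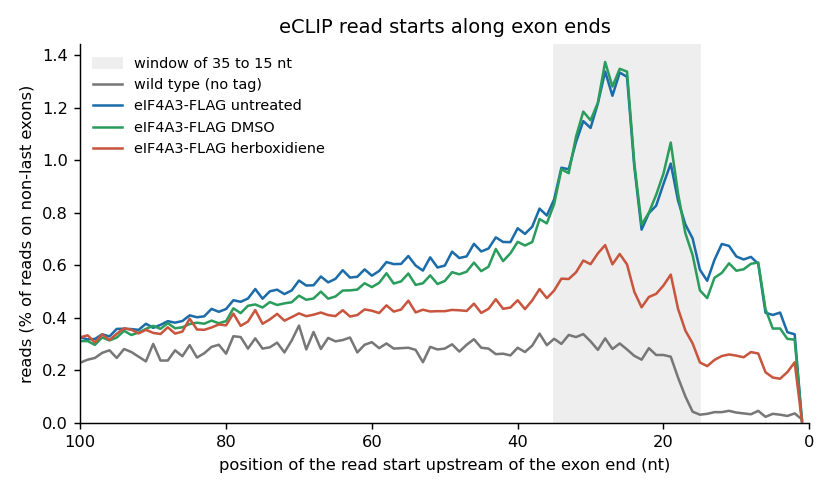
Read starts by distance (nt) upstream of the exon end, as percent of the reads on exons other than the last, with 1 line per eCLIP group and the window of 35 to 15 nt shaded. The tagged groups peak at 28 nt, where 1.34% of untreated, 1.37% of DMSO and 0.676% of herboxidiene reads started, beside 0.321% in wild type.

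Genes of the light-harvesting antenna were among those with the highest ratio of eIF4A3-FLAG to wild-type reads. LHCB2.1 had 1428 eIF4A3-FLAG reads and 0 wild-type reads, which is 24.3-fold higher after scaling against a floor of 3 reads for the group (lower bound of the exact interval 19.7). LHCB3 had 1494 reads against 1 (ratio 76.3, 13.7 to 3015) and LHCA1 3075 against 8 (19.6, 9.95 to 45.5). LHCB2.2, LHCB5 and LHCA3 were also among the 10 genes with the highest lower bounds. The other 4 were PRR7, a transcriptional repressor of the circadian clock, with 2491 reads against 5 (25.4, 10.9 to 78.4), FBP, a fructose bisphosphatase, at 43.0 (11.9 to 355), the DNA damage kinase gene ATM at 44.1 (7.90 to 1744) and AT3G54500 at 62.1 (11.1 to 2454). The lowest ratios included AT5G51300 (204 against 158 reads, 0.0659, 0.0533 to 0.0817) and BES1 and BEH2, transcription factors of brassinosteroid signalling, at 0.0698 (0.0494 to 0.0990) and 0.0718 (0.0515 to 0.101). They also included ENODL2, FBA7, an aldolase, PLP9, AT4G34950, AT2G42270, AT4G25620, and KCS10, an enzyme of fatty acid elongation, with 330 against 180 reads (0.0936, 0.0778 to 0.113). EIF4A-III (AT3G19760), the gene of the tagged protein, had 209 reads against 0, which is 3.56-fold higher against the floor (lower bound of the exact interval 2.87). Wild type lacks the tagged copy, so reads of that copy may add to this ratio.

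Among 4366 nuclear protein-coding genes with at least 100 reads in both groups together, 1594 (36.5%) were at least 2-fold higher and 645 (14.8%) at least 2-fold lower in eIF4A3-FLAG than in wild type. The median log2 ratio was 0.53. Scaling by the median of ratios shifts every log2 ratio down by 0.48 and gives 1051 genes higher and 1028 lower. Wild type had 0 reads for 103 of these genes. Among genes with at least 20 wild-type reads, 88 were higher and 456 lower.

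The nuclear photosynthesis genes had a median log2 ratio of 3.45 over 17 measured members, the 100 percentile of 10000 random lists matched on read number. Of these, 12 were at least 2-fold higher, including LHCA4 (4908 against 23 reads, 10.9, 7.25 to 17.2), and 1, RBCS1B, was lower (0.286, 0.209 to 0.398), joined by RBCS2B under the median of ratios. Rubisco activase RCA stood at 1.13 (0.968 to 1.33) and the Rubisco small subunit RBCS1A at 0.889 (0.766 to 1.04). LHCB2.1 and LHCB2.2 have nearly identical sequences, so the split of reads between them is uncertain. The list of exon junction complex and nonsense-mediated decay factors had a median of 1.45 (percentile 94.0), with 4 of 6 members higher. Among them were UPF3 (3.97, 1.69 to 12.3) and UPF1, named LBA1 here, at 2.1 (1.38 to 3.36). Another was EIF4A-III, the gene of the tagged protein, whose ratio may include reads of the tagged copy that wild type lacks. Under the median of ratios LBA1 was not among the higher members. Of 7 clock genes, PRR7, PRR5, GI and TOC1 were higher and ELF3 was lower (0.177, 0.138 to 0.229), for a median of 1.00 (percentile 88.2), and TOC1 lost its call under the median of ratios. The clock-regulated RNA-binding protein gene GRP7 had the most reads of this list, with a ratio of 0.805 (0.699 to 0.932). The 18 SR protein genes, which encode splicing regulators, had a median of 0.24 (percentile 69.3), which turns to -0.24 under the median of ratios. SR30, SR34, SR34a and RS2Z33 were at least 2-fold higher and RS41 was lower (0.315, 0.254 to 0.395), while under the median of ratios SR30 and SR34a were higher and RS31, RS40 and RS41 lower. The 3 measured genes of the ABA and osmotic stress list had a median of -0.27 (percentile 13.5), and HAB1 was at least 2-fold lower under the median of ratios alone. The 2 ribosomal protein genes P40 and BBC1 had a median of 0.26 (percentile 51.3), which turns to -0.22 under the median of ratios.

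The comparison of herboxidiene with DMSO asks how inhibited splicing alters eIF4A3 signal. Spliced reads made up 14.2% (14.1 to 14.2) of all reads with herboxidiene and 31.2% (31.1 to 31.2) with DMSO. Among reads assigned to genes, the spliced share was 21.6% against 41.9%. The share of reads with intron sequence was 12.0% against 5.01%, near the 13.6% of wild type. At exon ends, 10.9% (10.8 to 11.0) of reads on exons other than the last started 35 to 15 nt upstream with herboxidiene, and 20.9% (20.8 to 21.0) with DMSO, a ratio of 0.521 (0.516 to 0.525). The ratio was 0.398 (0.388 to 0.408) for first exons, 0.569 (0.564 to 0.575) for internal exons and 0.789 (0.781 to 0.798) for the window 65 to 45 nt upstream. Last exons took 22.2% of exonic reads with herboxidiene and 16.6% with DMSO. Both groups were sequenced on the same flow cell.

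**Figure D2:**
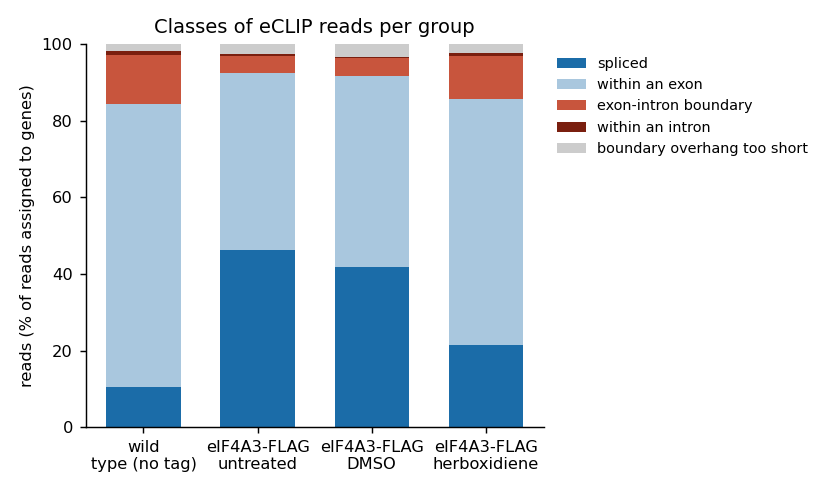
Classes of eCLIP reads as percent of the reads assigned to genes (stacked bars, 1 bar per group). Spliced reads made up 10.5% in wild type, 46.2% in untreated eIF4A3-FLAG, 41.9% with DMSO and 21.6% with herboxidiene.

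Several genes of stress and abscisic acid (ABA) responses were among those with the highest ratios of herboxidiene to DMSO eCLIP reads. The stress-induced F-box gene FBS1 had 361 reads with herboxidiene and 19 with DMSO (ratio 22.6, 14.2 to 37.9). LTI78, a dehydration and cold response gene also known as RD29A, had 8194 and 1141 (8.53, 8.02 to 9.08). MYB96, a transcription factor of ABA responses, was at 9.34 (7.01 to 12.7), the transcription factor gene WRKY48 at 14 (10.6 to 18.6) and SRO5 at 12.6 (9.41 to 17.1). The other genes of the 10 with the highest lower bounds were AT2G20670 (13.4, 11.7 to 15.3), the histone gene H2AXA (11.6, 8.49 to 16.1), SIP1, AT2G43620 and AT4G33920. At the other end, AT2G15880 had 142 reads with herboxidiene and 8588 with DMSO (0.0196, 0.0165 to 0.0232), AT5G02170 1 and 265 (0.00448, 0.000113 to 0.0252), and MBAC1, a mitochondrial amino acid carrier, 13 and 797 (0.0194, 0.0103 to 0.0333). The beta-amylase gene BAM5 had 0 and 146 reads and AT1G17990 0 and 104. Against a floor of 3 reads for the group, their ratios are 0.0244 and 0.0343, and the upper bounds of the exact intervals are 0.0304 and 0.0429. The list ended with AK3, an aspartate kinase (4 and 252 reads), AT5G16960 (14 and 552), EPR1, a clock-related MYB gene (1 and 110), AT5G02180 (12 and 291) and AtSPO22 (5 and 152). EIF4A-III had 112 reads with herboxidiene and 93 with DMSO (1.43, 1.08 to 1.90).

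Of 3683 genes with at least 100 reads in both groups together, 452 (12.3%) were at least 2-fold higher and 764 (20.7%) at least 2-fold lower with herboxidiene. The median log2 ratio was -0.22. The median of ratios moves every log2 ratio up by that amount and gives 618 higher and 539 lower.

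The ABA and osmotic stress list had a median log2 ratio of 1.95 over 5 measured members (percentile 99.9). LTI78, the ABA-signalling phosphatase PP2CA (730 and 108 reads, 8.03, 6.55 to 9.92) and COR15A (3.85, 2.70 to 5.61) were at least 2-fold higher, while ABI1 stood at 1.91 (1.62 to 2.26) and KIN1 at 1.45 (1.16 to 1.84). ABI1 passed 2-fold under the median of ratios, for 4 of 5 members. In total RNA, spliced junction reads of LTI78 had a ratio of 0.914 (0.837 to 0.996). The 17 photosynthesis genes had a median of 0.50 (percentile 86.8). LHCA1, LHCA4 and RCA stood at 1.4, 1.23 and 1.19, and LHCB2.3 was the sole member at least 2-fold lower (0.260, 0.199 to 0.335). Under the median of ratios LHCB4.1 and LHCA2 were at least 2-fold higher. The 7 clock genes had a median of 0.47 (percentile 77.0), with CCR1 higher (2.41, 2.08 to 2.80), PRR7 lower (0.260, 0.224 to 0.30) and GRP7 at 1.66 (1.51 to 1.83). The 18 SR genes had a median of -0.32 (percentile 15.1), with SR45 higher (2.12, 1.71 to 2.64), SR45a (0.481, 0.376 to 0.611) and RSZ22a (0.440, 0.298 to 0.638) lower, and SR34 at 1.16 (1.05 to 1.28). Under the median of ratios SR45 and RS2Z32 were higher and no SR gene was at least 2-fold lower. The exon junction complex and decay factors had a median of -0.10 (percentile 52.0), which turns to 0.12 under the median of ratios. UPF3 was the member that was at least 2-fold lower (0.491, 0.376 to 0.637), a call that ends under the median of ratios. The heat shock list had a median of 0.65 over HSP70 (2.32, 1.94 to 2.79) and HSP101 (1.06, 0.906 to 1.24), at percentile 81.8. The ribosomal protein genes P40 and BBC1 had a median of 0.63 (percentile 87.9).

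Reads with intron sequence were a larger part of the eCLIP signal with herboxidiene in most genes. Of the unspliced and spliced reads together, 35.6% (35.5 to 35.8) were unspliced with herboxidiene and 10.6% (10.5 to 10.7) with DMSO, beside 9.66% in untreated eIF4A3-FLAG and 56.2% in wild type. Among 4125 genes with at least 10 such reads in both treatments, 2792 (67.7%) had a share at least 10 points higher with herboxidiene and 91 (2.21%) at least 10 points lower. The anthocyanin regulator MYBL2 had 16.5% (11.8 to 22.6) with DMSO and 92.7% (88.0 to 95.7) with herboxidiene, and the SR gene RS40 15.5% (12.1 to 19.8) and 71.8% (65.8 to 77.1). For LTI78 the shares were 5.94% (3.74 to 9.31) and 42.7% (39.4 to 46.0). LHCA4 stood at 4.61% (3.27 to 6.47) and 3.12% (1.98 to 4.88).

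Total RNA of plants of the same genotype and treatments addresses the effect of herboxidiene on splicing itself. Of 38017 introns with at least 10 junction reads at the 5′ splice site in both conditions, 11963 (31.5%) had an unspliced share at least 10 points higher with herboxidiene and 1641 (4.32%) at least 10 points lower. Pooled over these introns, the unspliced share was 4.39% (4.36 to 4.41) with DMSO and 11.5% (11.4 to 11.5) with herboxidiene. Of 8493 genes, 5769 (67.9%) had at least 1 intron in the higher set and 1261 at least 1 in the lower set. The higher set held 43.9% of first introns, 28.2% of middle introns and 33.8% of last introns. Pooled shares with DMSO and herboxidiene were 4.06% and 13.4% for first introns, 3.28% and 8.54% for middle introns, and 8.29% and 18.15% for last introns. Medians over introns were 1.27% and 11.8% for first, 1.14% and 5.26% for middle, and 1.16% and 7.14% for last introns. The higher pooled share of last introns with DMSO is thus not seen in the typical intron. Simulated introns with no change gave 2467 higher and 2298 lower from counting error at the same depth, more than the 1641 lower introns observed. The simulation took each intron's share from both conditions pooled, so rises with herboxidiene entered it and can raise these numbers. The simulated 2298 and the observed 1641 are therefore not directly comparable. The intervals of both shares lay apart for 4543 introns higher and 41 lower with herboxidiene.

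The intron with the largest difference among those with at least 50 reads in both conditions lies on chromosome 4 at 8390041 to 8390118 (TAIR10) in AT4G14620 and the overlapping AT4G14622. It was unspliced in 0 of 68 reads with DMSO (interval up to 5.35%) and in 30 of 52 with herboxidiene (57.7%, 44.2 to 70.1). The first intron of the bromodomain gene GTE7 (chromosome 5, 26226695 to 26226787) had 0% (up to 4.23%) and 53.5% (43.8 to 62.9). Intron 2 of the NAC transcription factor gene ATAF1 (chromosome 1, 268995 to 269082) had 4.29% (1.47 to 11.9) and 57.7% (48.1 to 66.7). Introns of CRK2, a receptor-like kinase, MYBL2, AT5G57710, PP2-A11, AT1G02660 and AT1G02610 complete the set, with differences of 52.3 to 47.8 points. The largest differences in the other direction were smaller. Intron 6 of AT4G30690 (chromosome 4, 14961707 to 14961810) had 26.6% (21.2 to 32.8) with DMSO and 8.41% (4.49 to 15.2) with herboxidiene, and intron 9 of ER, the ERECTA receptor kinase gene (chromosome 2, 11212112 to 11212204), 17.8% (11.7 to 26.1) and 2.70% (0.744 to 9.33). Introns of ALDH7B4, SCPL13, IMPA-4, AT3G11560, ALATS, AT5G05200, CYP97B3 and SEX1 were also in this set. At the 3′ splice site the unspliced share of IMPA-4 was not lower with herboxidiene, and that of ALDH7B4 was 35.1% with DMSO and 32.7% with herboxidiene.

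The ABA and osmotic stress genes had the largest differences of the lists in total RNA. Their median was 33.1 points (the 100 percentile of random lists), beside 6.63 points over all genes, and 7 of 8 members were at least 10 points higher with herboxidiene. The unspliced share of LTI78 was 6.08% (5.04 to 7.33) with DMSO and 39.3% (36.6 to 42.0) with herboxidiene. ABI1 had 9.10% and 42.5%, KIN1 3.24% and 48.4%, and RAB18 was the member below the threshold, with a mean difference of 5.13 points. The photosynthesis genes had the lowest percentile of the lists (0.13), with a median of 0.41 points over 16 members, and LHCB2.3 alone was above 10 points (2.16% with DMSO and 18 of 90 reads with herboxidiene). Among 7 clock genes (median 8.59 points, percentile 94.4), PRR5 (9.82% and 40.3%), TOC1 (8.82% and 25.9%) and GI (4.33% and 21.0%) were higher. Of 14 SR genes, 7 were higher, with a median of 8.78 points (percentile 83.3), led by SC35 with a mean difference of 31.6 points. HSP70, HSP101 and HSP90.1 were all higher, with a median of 21.7 points (percentile 81.9). The medians were 4.07 points (percentile 43.7) for the exon junction complex and decay factors, where UPF3 alone was higher, 4.81 (percentile 54.8) for ribosomal proteins, where RPSAb alone was higher, and 0 (percentile 10.7) for the 2 measured genes of the splicing factor SF3B.

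**Figure D3:**
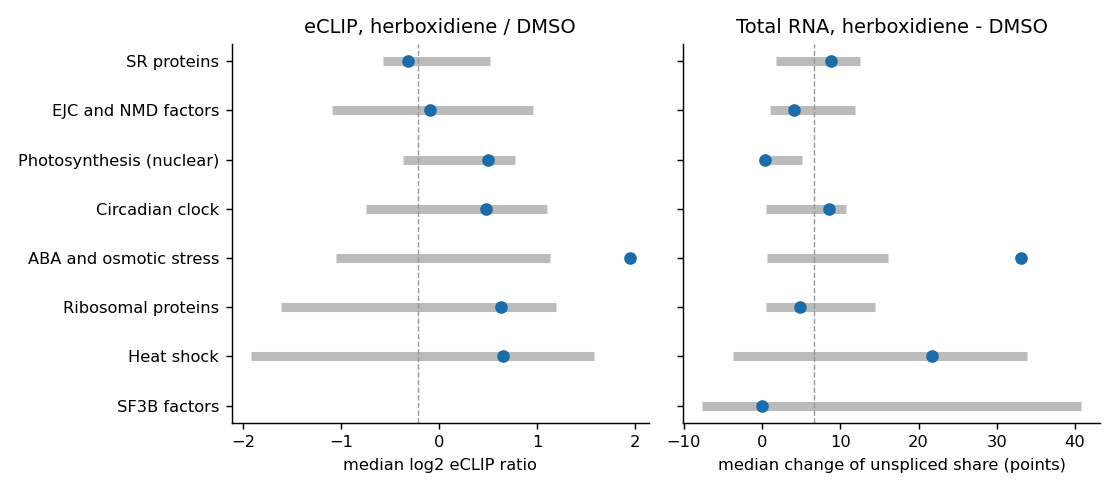
Gene list medians (points), the range of 95% of random lists (bars) and the median of all genes (dashed line) for the log2 ratio of eCLIP reads (left) and the change of the unspliced share in percentage points (right), herboxidiene against DMSO. The ABA and osmotic stress list lies beyond the random range at 1.95 and 33.1 points, and on the left the exon junction complex list turns from -0.10 to 0.12 under the median of ratios.

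Introns that were less spliced in total RNA with herboxidiene also had more unspliced eCLIP reads. Across 4182 introns with at least 10 reads in every group, the change of the unspliced share in eCLIP followed that in total RNA with a Spearman's rho of 0.416 and a Pearson's r of 0.444. At a minimum of 30 reads, rho was 0.614 over 889 introns. Introns are not independent replicates, so no p-value is given. Of 1236 introns at least 10 points higher in total RNA, 957 were also at least 10 points higher in eCLIP, as were 2357 of all 4182 introns. The median eCLIP difference was 6.67 points for introns within 2 points in total RNA and 41.1 points for those at least 20 points higher. In MYBL2, intron 2 had 23.5% and 95.3% unspliced eCLIP reads with DMSO and herboxidiene, beside 2 of 102 and 26 of 50 reads in total RNA. For the first intron of PP2-A11 the eCLIP shares were 7.14% (2 of 28 reads) and 82.4% (14 of 17).

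The share of eCLIP reads at exon ends was also compared by the splicing of the intron that follows. Before introns whose unspliced share moved by less than 2 points in total RNA, the share at exon ends was 21.9% with DMSO and 14.3% with herboxidiene, a ratio of 0.653. Before introns at least 20 points higher, it was 18.0% and 5.37%, a ratio of 0.297. Before introns more than 2 points lower, the ratio was 0.710. Reads in this window were nearly all spliced, so the share can fall before less spliced introns without a change in eIF4A3 binding.

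**Figure D4:**
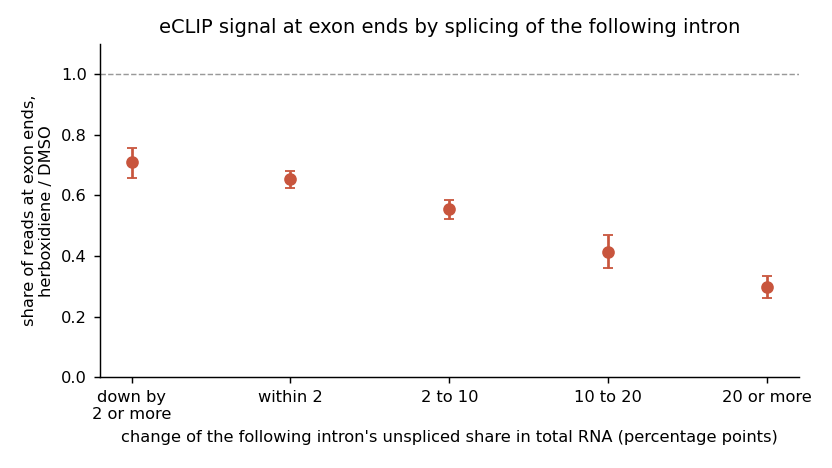
Ratio of the share of eCLIP reads at exon ends (35 to 15 nt upstream), herboxidiene over DMSO, by the change of the following intron's unspliced share in total RNA (percentage points). Points are ratios with 95% intervals from resampling genes, and they go from 0.710 before introns with a lower unspliced share to 0.297 before introns at least 20 points higher.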

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

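The read classes in this part entered no comparison above, they were set against wild type after the data were seen, and no explanation was tested for them. Shares are of all reads without organellar and ribosomal DNA reads. Reads spliced at a junction outside the annotated transcript were 3.87% in untreated eIF4A3-FLAG and 1.98% with DMSO, above 1.51% in wild type, while herboxidiene had 1.49%. With organellar and ribosomal DNA reads kept, this order turns, since wild type then had 13.3%. Reads with both a splice junction and intron sequence were 1.25% in untreated eIF4A3-FLAG, 1.39% with DMSO and 0.767% with herboxidiene, above 0.533% in wild type. Reads on exons of overlapping genes were 3.02% in untreated eIF4A3-FLAG and 3.52% with herboxidiene, above 2.83% in wild type, while DMSO had 2.75%. With the removed reads kept, wild type had 2.25%, below DMSO as well.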

How the results depend on the processing

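The alternatives chosen after the data were seen were the shared flow cell, the minimum of wild-type reads, intervals that lie apart, the deposited ratio, 1 deposited part or the same transcript for genes and unspliced shares, removal of ribosomal DNA reads and the aligned length. Of the alternative values, 28 stayed within a tolerance of 1.5 times for counts and of the 95% interval for other values, among them the 3′ splice site (12073 introns higher, 1742 lower), the deposited ratio (13308 and 2100), and the gene counts from the first deposited part or from genes on the same transcript. This tolerance is wide for counts: it takes in 17530 introns higher with no minimum, and the median of ratios for herboxidiene over DMSO, where 618 genes higher and 539 lower turn which direction is larger. The 28 leave out list percentiles, since the median of ratios adds 1 constant to every gene, and the removal of organellar reads from the tagged groups, which hold none. The 27 that moved are as follows. In total RNA, a minimum of 30 reads gave 3784 introns higher and 154 lower, a difference of 0.2 gave 6073 and 327, and intervals that lie apart gave 4543 and 41, while no minimum gave 4250 lower. For eIF4A3-FLAG over wild type, the median of ratios gave 1051 genes higher and 1028 lower, the shared flow cell 1046 and 399, at least 20 wild-type reads 88 higher, and a minimum of 20 reads 2754 lower. For herboxidiene over DMSO, a minimum of 20 reads gave 930 and 2441. A minimum of 30 reads gave 1036 genes with a higher and 13 with a lower unspliced eCLIP share, and a rho of 0.614 across introns. In the first deposited part alone, spliced shares were 10.5% in wild type, 46.2% in eIF4A3-FLAG, 41.9% with DMSO and 21.6% with herboxidiene. The wild-type share was 5.49% without organellar reads and 7.42% also without ribosomal DNA reads. Internal exons of at least 100 nt gave exon-end ratios of 3.78 over wild type and 0.497 over DMSO, and the window of 30 to 20 nt gave 0.514 over DMSO. Counts under stricter or looser minimums differ in part because fewer or more genes and introns are counted. The minimum of wild-type reads also favours genes with a low ratio. For the rest the cause was not tested. No paired analysis was possible because the replicates were merged, and for the same reason leaving out each replicate and a replicate block were not run. The 96768 wild-type reads assigned to genes limit the ratios of genes with few wild-type reads.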

Other observations

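The tests of aligned length, of the background share at exon ends, of all junction reads of ABA genes and of the removal of organellar reads were chosen after the results were seen. Few of the measured genes that were 2-fold higher or lower in eCLIP with herboxidiene were so in spliced RNA. Of 452 genes at least 2-fold higher in eCLIP, 335 were measured in total RNA. Of these, 16 were at least 2-fold higher in spliced junction reads (median log2 0.15). Of 764 lower genes, 582 were measured, and 52 of these were at least 2-fold lower (median -0.23). A gene needed at least 100 spliced reads in both conditions together, over introns counted in both. Genes with little transcript can therefore be missing. Spliced reads also leave out unspliced transcripts, so a higher transcript level with herboxidiene can be understated. Across 3025 genes, Spearman's rho of the eCLIP ratio with the spliced read ratio was 0.228. FBS1 had a ratio of spliced reads of 1.43 (1.24 to 1.64), SRO5 1.12 (0.945 to 1.32) and LTI78 0.914 (0.837 to 0.996). Among the 10 named genes with the lowest eCLIP ratios, the carrier gene MBAC1 was at 0.321 (0.233 to 0.435) and the clock-related gene EPR1 at 0.383 (0.302 to 0.482). The others had no total RNA value, so for them a lower transcript level could not be examined. The SR list had a median log2 ratio of spliced reads of 0.33 (percentile 98.9) and the photosynthesis list -0.16 (percentile 2.79). Exon junction complex and decay factors stood at 0.22 (percentile 88.5), ribosomal proteins at 0.29 (89.0), ABA genes at 0.01 (58.7) and clock genes at -0.07 (38.0).

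Genes with a high ratio of eIF4A3-FLAG to wild type tended to have a low ratio of herboxidiene to DMSO, with a Spearman's rho of -0.249 across 3138 genes. PRR7 followed this, at 25.4 in the former and 0.260 in the latter, while LHCA1 (19.6 and 1.4), LHCB5 (19.9 and 1.65), LHCA3 (15.8 and 1.66) and LHCB3 (76.3 and 1.41) did not. The polyubiquitin gene UBQ11 and the jasmonate repressor gene JAZ1 had eCLIP ratios of 2.23 (2.08 to 2.39) and 4.70 (3.99 to 5.56) with herboxidiene. Their ratios of spliced reads in total RNA were 1.73 (1.45 to 2.07) and 1.12 (0.891 to 1.41). Their unspliced shares in total RNA were 10.7% and 7.76% with DMSO and 48.8% and 36.8% with herboxidiene. Spliced reads leave out the unspliced transcripts, so their ratios understate the change of all transcripts and cannot be set directly against the eCLIP ratios. These genes were named after their values were seen.

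The share of eCLIP reads at exon ends was lower with herboxidiene. Shorter aligned reads are argued against, since reads aligned over at least 60 nt gave a ratio of 0.525. Lost splicing of the following intron may contribute, as the log2 ratio before introns at least 10 points less spliced differed by -0.91 (-1.05 to -0.76, resampling genes) from that before introns that moved by less than 2 points, although these too had a ratio of 0.653. However, reads in the window were nearly all spliced. Of spliced and exon-intron boundary reads there, 2.62% were boundary reads with herboxidiene and 0.528% with DMSO. Between 61 and 100 nt these shares were 23.6% and 4.73%. A lower share before less spliced introns can follow from fewer spliced reads alone, so this test cannot tell whether eIF4A3 binding changed. A larger share of background reads stays open. The 4 features of the reads gave background shares of 0.533 to 0.816, a spread of 0.283 that neither meets nor excludes a single share. Wild type had few starts very near exon ends, which can alter its spliced share and so these estimates. Moreover, no untagged plants were treated with herboxidiene.

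ABA and osmotic stress genes had more eCLIP reads with herboxidiene, for which a larger share of background reads stays open. A mixture of DMSO and wild-type reads at a background share of 0.644 gave a median log2 ratio of -1.43, and the observed median lay above it by 3.37 (2.87 with wild-type genes at the floor), but the mixture takes untreated wild type as the background and no untagged plants were treated with herboxidiene. More transcript in total RNA is argued against as the cause of the whole pattern, as the 5 members had a median log2 ratio of spliced reads of -0.088 relative to all genes and a highest value of 0.25, below the 0.97 that this explanation needed. With unspliced junction reads included, the median was 0.41 and the highest value 0.78, in ABI1, whose eCLIP value was 0.93, so for this gene it stays open. An effect of herboxidiene on eIF4A3 binding was not tested.

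Organellar reads made up 5.71% of wild-type reads and 0 reads in each tagged group, although the tagged groups were deeper. A removal of organellar and ribosomal RNA reads from the sets of the tagged groups only stays open, since these same counts raised it and no other value tests it. If no reads were removed, the 0 organellar reads with herboxidiene would argue against a background like that of wild type. The larger share of background reads left open above therefore depends on this question. No biological explanation was tested.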
